A study of Homo sapiens with 8 samples.

How the data were processed

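Small RNA of HEK293 cells was measured in 8 libraries, 4 from cells transfected with a scramble control mimic and 4 from cells transfected with a tRNA-Asp-GTC 3′ tDR mimic. Per the labels, the mimics were given at 50 nM and the cells collected after 48 h, with TRIzol RNA and OTTR-seq libraries. Groups and replicate numbers were taken from the labels. The genome build is hg38 per the submitters' processing notes; the aligner, the counting tool and the annotation are not given in the sources used here.

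The deposited raw file holds whole-number counts per small RNA feature, with 2964 entries, of which 2 (scr and scr2) are not genes and stayed out of library sizes and tests. The second deposited file holds a normalized signal. Comparison with the raw file showed that the authors divided each count by a factor per library, with separate factors for tRNA and precursor features and for all others; how the factors were estimated is not given in the sources used here. Both files count whole tRNAs and precursor loci and do not separate 3′ from 5′ fragments.

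Counts summed over features were 8235808, 10208695, 4016295 and 10246336 in scramble libraries 1 to 4 and 6910186, 7585015, 8007025 and 7115041 in tDR libraries 1 to 4. At these depths a count of 0 leaves room for 3 counts, between 2.91e-05% and 7.43e-05% of a library. Features of a family whose counts differed by at most 10% or 3 counts in every library were treated as drawing on the same reads, which gave 2259 sets. Library identity was checked over 12 replicate pairs, and the lowest chi-square per degree of freedom was 16.3, so no pair was a copy.

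Features were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM factors, robust quasi-likelihood fit and F test without covariates, Benjamini-Hochberg adjusted p below 0.05. This left 1761 features tested and 1201 not tested, with a biological coefficient of variation of 19%. SE was the size of the log2 fold change divided by the square root of F. CPM values are TMM-scaled unless they concern scr and scr2, which are per total count. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 3 tested members, 33 in all. The same lists were tested with an estimated correlation and with fry. Class shares used the largest feature of each gene family as that family's count, with an exact two-sided permutation test over 70 arrangements and Benjamini-Hochberg adjustment over 33 classes.

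The comparisons, tests, lists, alternatives and the rule for naming features were set before the data were examined. That rule names the tRNA-Asp-GTC features with the highest counts and lowest p, the 10 largest rises and 10 largest falls among called features whose groups do not overlap and whose mean count is at least 20, for each list up to 3 members with the lowest p and the most abundant member, the 3 most abundant features, and hsa-miR-210-3p. The lists were the tRNA-Asp-GTC features, other whole tRNAs, tRNA isotypes, precursor tRNAs, microRNAs with the miR-17-92 and let-7 families and kidney, stress and immune, blood, endothelial and neural markers, C/D box and H/ACA box snoRNAs, scaRNAs, snRNAs, rRNAs and other RNA polymerase III transcripts. Lists for 3′, 5′ and internal tRNA fragments, mitochondrial tRNAs, histone genes, the miR-200 family and the hypoxia microRNA had no tested member. The split into 17 RNA families and 12 further named features were chosen after the values were seen.

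The fit was tested on data simulated with the library sizes and the means and dispersions of the 1761 tested features. Of these, 1702 passed the filter again on the simulated counts. Among those that passed, it recovered 80 of 97 features changed by a log2 of 1 (82.5%) and 100 of 100 changed by 2. It made 8 false calls among 1505 unchanged features. In a second simulation camera called a shifted list of 30 features higher and did not call an unchanged one. Both simulations drew each feature independently, without shared reads, whereas the estimated correlation was 0.41 in the microRNA list and 0.71 in the miR-17-92 family. So they do not show how the fit or camera behaves with correlated features.

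The alternatives set in advance were DESeq2 size factors, total counts, TMM without Asp-GTC features or on microRNAs alone, no filter, a mean count of at least 50, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block, limma on log2 of the deposited normalized signal plus 1, and leaving out each library. Chosen after seeing the data were each set of shared reads taken once, the authors' factors, leaving out tDR libraries 3 and 4 together, sums over all features for the shares and sign flips of same-numbered differences. Coordinates are those of GENCODE release 29 for GRCh38 and, for tRNAs, of RefSeq for GRCh38; features named Y_RNA with a number could not be placed. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The balance of 3′ to 5′ tRNA fragments was planned and left out, since the files do not separate them.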

Results

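Small RNA was profiled in HEK293 cells, a human embryonic kidney line, 48 h after lipid transfection with 50 nM of a synthetic RNA. In 4 libraries the cells had received a mimic of the 3′ tRNA-derived small RNA (tDR) of tRNA-Asp-GTC, and in 4 libraries a scrambled control mimic. Libraries were prepared by OTTR-seq, in which a reverse transcriptase adds both adapters while copying the RNA. The series title places this fragment among hypoxia-responsive small RNAs linked to kidney protection and RNA autophagy. The comparison asks which small RNAs differ once the fragment is supplied. The count table held 2962 small RNA features, and the counts over them summed to 8235808, 10208695, 4016295 and 10246336 in scramble libraries 1 to 4 and to 6910186, 7585015, 8007025 and 7115041 in tDR libraries 1 to 4. Of 1647 features with at least 100 counts, 137 carried exactly the counts of another feature in all libraries, so the same reads are counted at more than 1 gene copy. With features of equal or nearly equal counts taken once, the libraries held between 1488556 and 3924729 counts. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

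The transfected sequences were examined first, as a check of the labels. A row named scr2, which the labels do not explain, held 4863 ± 985 CPM (counts scaled to library size) in the scramble libraries and 17.6 ± 11.9 CPM in the tDR libraries (SD, n = 4 each, exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give, two-sided). It was higher in 4 of 4 scramble libraries than in any tDR library, by 276-fold on the means. Its share was 0.352% (95% exact binomial interval 0.348 to 0.356%), 0.473% (0.468 to 0.477%), 0.556% (0.548 to 0.563%) and 0.565% (0.56 to 0.569%) in scramble libraries 1 to 4, and 0.00347% (0.00305 to 0.00394%), 0.00144% (0.00118 to 0.00173%), 0.000737% (0.000561 to 0.00095%) and 0.00139% (0.00113 to 0.00169%) in tDR libraries 1 to 4; the intervals cover counting error only. A second such row, scr, held 25, 27, 4 and 7 counts in scramble libraries 1 to 4 and 29, 0, 1 and 0 in tDR libraries 1 to 4, where 3 counts are the limit that a count of 0 allows. Its means were 1.83 ± 1.17 CPM and 1.08 ± 2.08 CPM (SD, n = 4 each, exact permutation p = 0.629). The main isodecoder of the mimicked tRNA, tRNA-Asp-GTC-2, gave 26650 ± 4068 CPM in the scramble libraries and 28670 ± 4377 CPM in the tDR libraries (TMM-scaled, SD, n = 4 each). Its log2 fold change of 0.11 (SE 0.14) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.757).

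The other tRNA-Asp-GTC features did not pass either. tRNA-Asp-GTC-1 stood at 1602 ± 374 and 1932 ± 275 CPM, a log2 fold change of 0.27 (SE 0.17, edgeR adjusted p = 0.372), and tRNA-Asp-GTC-3 at 58.8 ± 19.4 and 46.0 ± 6.68 CPM, a log2 fold change of -0.35 (SE 0.19, edgeR adjusted p = 0.318). Among the precursor loci, tRNA-Asp-GTC-2-1, tRNA-Asp-GTC-2-2 and tRNA-Asp-GTC-2-3 carried identical counts and a log2 fold change of 0.54 (SE 0.26, edgeR adjusted p = 0.229). They lie on chromosome 1 (GRCh38) at 161440825 to 161440896, 161448243 to 161448314 and 161455624 to 161455695. The loci tRNA-Asp-GTC-2-8 and tRNA-Asp-GTC-2-9 gave log2 fold changes of 0.33 and 0.0014. Of the 10 tested features of this tRNA, 0 were called by edgeR, also when adjusted over the list alone, and 5 had an unadjusted p below 0.05. These 5, tRNA-Asp-GTC-2-1 to tRNA-Asp-GTC-2-5, share identical counts and so are 1 of the 6 sets of reads behind the 10 features. Of the 8 named here DESeq2 and limma-voom called 0. The camera test of the list gave adjusted p = 0.125. The list was called higher without scramble library 2 (adjusted p = 0.046), tDR library 1 (0.0282) or tDR library 2 (0.0277), but in none of these with an estimated correlation (adjusted p from 0.792 to 0.998). The direction of tRNA-Asp-GTC-2 depended on the scaling, with log2 fold changes of -0.044 under total counts and -0.10 with the authors' factors. The table counts whole tRNAs and precursor loci and has no separate row for 3′ fragments, so a gain of the mimic was read only on top of the endogenous tRNA.

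**Figure D1:**
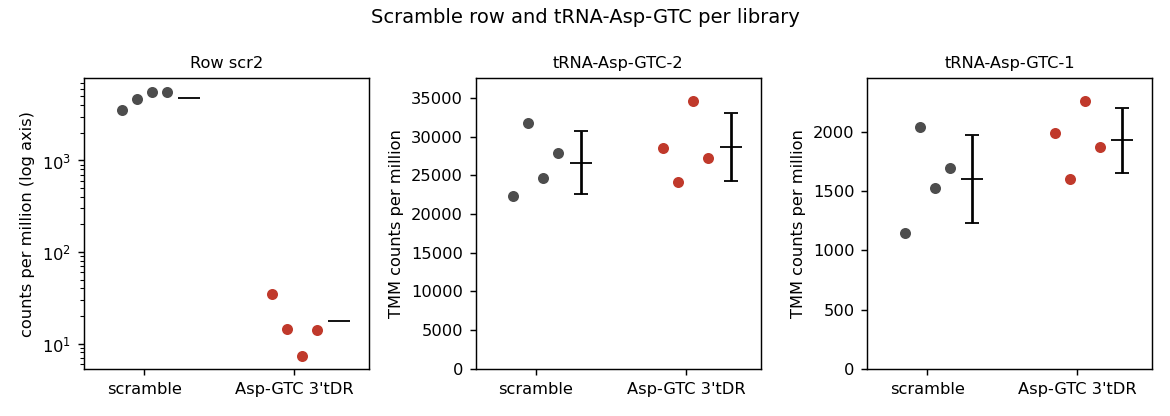
CPM in each library for the row scr2 (left, log axis), tRNA-Asp-GTC-2 (middle) and tRNA-Asp-GTC-1 (right), in scramble and Asp-GTC 3′ tDR libraries; points are libraries, horizontal marks are group means and whiskers, in the tRNA panels, are SD (n = 4). The row scr2 averages 4863 CPM in scramble and 17.6 CPM in tDR libraries, while the groups overlap for both tRNAs.

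After the tDR mimic, counts rose at some copies of U1, U2, Y RNA and 5S rRNA genes and fell for 9 microRNAs. Most tested copies of these gene families were not called, and the median Y RNA and 5S rRNA copies stood at -0.078 and -0.079 on the log2 scale. U1 and U2 are the small nuclear RNAs that recognise the 5′ splice site and the branch point of introns. Y RNAs are short RNA polymerase III transcripts bound by the Ro60 protein, and 5S rRNA is a component of the large ribosomal subunit. Among the strong rises were RNY4P10, a copy of the Y4 RNA gene, from 154 ± 4.94 to 403 ± 56.6 CPM, and RNVU1-19, a variant U1 gene, from 180 ± 20 to 462 ± 99.3 CPM (SD, n = 4 each). Their log2 fold changes were 1.39 (SE 0.15, edgeR adjusted p = 1.3e-05) and 1.36 (SE 0.17, edgeR adjusted p = 4.09e-05). Over all 1761 tested features, edgeR called 118 at an adjusted p below 0.05, 94 higher and 24 lower in the tDR libraries.

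Of the 94 higher features, 84 matched a name pattern for pseudogene or repeat copies, and the 94 form 75 sets of equal or nearly equal counts. The pattern also takes in the gene RMRP, which is not such a copy. How many of all tested features match it was not counted. By family, 22 of 59 U1 features rose and 0 fell, 11 of 51 U2 features rose and 0 fell, 26 of 314 Y RNA features rose and 4 fell, 14 of 107 5S rRNA features rose and 3 fell, and 7 of 64 7SK features rose and 0 fell. The family split was drawn after the values were seen, over 17 families. Tested as sets with camera, the U1 family was higher (adjusted p = 1.67e-11, but adjusted p = 0.384 with an estimated correlation), as was the 7SK family (adjusted p = 1.12e-06, but adjusted p = 0.384 with an estimated correlation). The U6atac and vault RNA families, of 6 and 4 features, were lower (adjusted p = 5.45e-05 and 0.0161, but adjusted p = 0.384 with an estimated correlation). By camera the U2 and 28S rRNA families were also higher (adjusted p = 0.0127 and 0.0036), and the snaR and 5.8S rRNA families lower (0.0107 and 0.0499). With an estimated correlation none of these passed (adjusted p from 0.629 to 0.747). The Y RNA and 5S rRNA families did not pass camera (adjusted p = 0.08 and 0.958). The limma test fry, which asks whether the genes of a set move one way on balance and does not compare them with other genes, passed for U1 (adjusted p = 0.0129), U6atac (0.0101) and vault RNA (0.0116), but not for 7SK (0.101). The lists fixed before the data were examined counted 36 snRNA features higher and 7 lower of 294 (49 and 15 adjusted over the list alone), 38 higher and 4 lower of 439 other RNA polymerase III transcripts (50 and 8 adjusted over the list alone), and 19 higher and 4 lower of 136 rRNA features (21 and 5 adjusted over the list alone). None of these 3 lists passed as a whole, with camera adjusted p of 0.773, 0.812 and 0.986. Without scramble library 2 their counts became 27 higher and 4 lower, 15 and 1, and 10 and 1. With the replicate block they became 22, 9 and 7 higher and 0 lower.

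Within the U1 family, RNU1-132P rose from 42.7 ± 5.93 to 115 ± 31.8 CPM (log2 fold change 1.44, SE 0.18), RNU1-22P from 34.7 ± 3.85 to 91.4 ± 23.1 CPM (1.40, SE 0.17) and RNU1-46P from 34.4 ± 3.92 to 88.5 ± 23.2 CPM (1.37, SE 0.18), each with edgeR adjusted p = 4.09e-05. RNU1-130P and RNU1-32P rose by log2 fold changes of 1.49 and 1.45 from 1.49 and 3.55 CPM. The call of RNU1-130P was lost without scramble library 3 or tDR library 2. The U1 gene itself, RNU1-1 (chromosome 1, 16514122 to 16514285), stood at 779 ± 33.6 and 1033 ± 131 CPM, a log2 fold change of 0.41 (SE 0.14) that did not pass edgeR (adjusted p = 0.0997). In the U2 family RNU2-7P rose from 95.7 ± 13.1 to 238 ± 45.6 CPM (log2 fold change 1.31, SE 0.17, edgeR adjusted p = 4.09e-05), while RNU2-1, whose counts nearly equal those of U2.10, stood at 10010 ± 339 and 9577 ± 605 CPM (log2 fold change -0.064, SE 0.12, edgeR adjusted p = 0.833). RNU1-1, RNU2-1, RNU2-7P, RNY4, RNY1, RNY3, RNY5, RNA5S1, RMRP, RNA28SN5, hsa-miR-222-3p and hsa-miR-24-3p were chosen after their values were seen. RNVU1-19 lies on chromosome 1 at 120850819 to 120850985, outside annotated protein-coding genes, and RNU2-7P on chromosome 13 at 20612161 to 20612338, in an intron of IFT88 (GRCh38, GENCODE release 29).

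Of the Y RNA genes, RNY4 was called. RNY4 (chromosome 7, 148963315 to 148963410), the Y4 gene, rose from 485 ± 44.9 to 822 ± 60.9 CPM (log2 fold change 0.76, SE 0.15, edgeR adjusted p = 0.0028). RNY1, RNY3 and RNY5 did not pass, with log2 fold changes of 0.33 (SE 0.15), 0.016 (SE 0.15) and 0.23 (SE 0.15) and edgeR adjusted p of 0.211, 0.966 and 0.409. The difference between Y4 and these genes was not tested. The copies RNY4P10 (chromosome 6, 33199601 to 33199696, in an intron of RXRB) and RNY4P7 (chromosome 2, 127798903 to 127798998, in an intron of WDR33) had nearly equal counts and rose by log2 fold changes of 1.39 and 1.32. Y_RNA.293 rose from 140 ± 5.03 to 383 ± 53.0 CPM (1.46, SE 0.15, edgeR adjusted p = 1.12e-05) and Y_RNA.122 from 2.64 ± 0.729 to 9.05 ± 1.03 CPM (1.78, SE 0.27). Y_RNA.646 and Y_RNA.172 fell, by 1.22 and 0.97 on the log2 scale (SE 0.35 and 0.29, edgeR adjusted p = 0.0376 and 0.0469). Both calls were lost without scramble library 2 or 4 or tDR library 2, 3 or 4 (adjusted p from 0.0517 to 0.161), with the replicate block and under scaling on microRNAs alone. The 4 lower Y RNA calls became 0 without scramble library 4, tDR library 3 or tDR library 4.

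In the rRNA list, 5S_rRNA.18 rose from 77.9 ± 7.53 to 182 ± 36.3 CPM (log2 fold change 1.22, SE 0.16, edgeR adjusted p = 4.7e-05). RNA5SP225 and RNA5SP259, with nearly equal counts, rose by log2 fold changes of 1.05 and 1.07, and RNA5SP257 by 1.48. The 5S gene RNA5S1 stood at 8494 ± 779 and 8040 ± 939 CPM (log2 fold change -0.079, SE 0.13, edgeR adjusted p = 0.812). All 5 copies of the 28S rRNA gene, with nearly equal counts, rose, with RNA28SN5 going from 28150 ± 3972 to 42710 ± 10770 CPM (log2 fold change 0.60, SE 0.16, edgeR adjusted p = 0.0233). This call was lost without scramble library 2, 3 or 4 or tDR library 2 (adjusted p from 0.0803 to 0.111). It was also lost under scaling on microRNAs alone (adjusted p = 0.065) and with the replicate block (adjusted p = 0.113). With each read set taken once, 0 of 1 28S rRNA features was called. The 18S rRNA copies RNA18SN2, RNA18SN3 and RNA18SN4, the features with the highest mean count, had a log2 fold change of 0.27 (SE 0.13, edgeR adjusted p = 0.227). RMRP, the RNA of the ribonuclease MRP complex that takes part in rRNA processing, rose from 63.1 ± 6.80 to 96.8 ± 9.32 CPM (log2 fold change 0.62, SE 0.14, edgeR adjusted p = 0.0119). RN7SL1, the signal recognition particle RNA, had a log2 fold change of -0.18 (SE 0.18, edgeR adjusted p = 0.643). 5_8S_rRNA.9, RNU6ATAC26P and RNU6-236P fell, by 0.98, 1.00 and 0.84 on the log2 scale (edgeR adjusted p = 0.0376, 0.0175 and 0.0383). These 3 calls were lost without tDR library 4 (adjusted p = 0.12, 0.0505 and 0.101), under scaling on microRNAs alone and with the replicate block. The call of 5_8S_rRNA.9 was also lost without scramble library 1, 2 or 3 or tDR library 2 or 3, and that of RNU6-236P without scramble library 2 or 3 or tDR library 2 or 3. RNU6ATAC26P is a copy of the minor spliceosome's U6atac gene.

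The count of changed features depended on the scaling and on single libraries. Total-count scaling shifted the median over all features to -0.13 and called 93 features, 54 higher and 39 lower, with 17 U1, 11 Y RNA and 1 7SK features higher. The call of RMRP was lost (adjusted p = 0.0737), as it was with the replicate block (adjusted p = 0.0812). Scaling on microRNAs alone shifted that median to 0.36 and called 158 features, 157 higher and 1 lower. The U2 family median turned from 0.11 to -0.041 under total counts, and the Y RNA, 5S rRNA and U6 family medians turned from -0.078, -0.079 and -0.21 to 0.24, 0.24 and 0.12 under scaling on microRNAs alone. Without scramble library 2 the count was 65, and without scramble library 3 it was 70. The number of lower calls also depended on single libraries. The 24 lower calls became 3 without tDR library 4 (84 higher), all microRNAs, and 1 with the replicate block, but 47 without tDR library 1 (117 higher). With all libraries 23 of the 24 did not overlap between the groups. These fits have fewer libraries or degrees of freedom, so a lost call need not mean a lost difference. The 26 Y RNA features called higher became 14 without scramble library 2, 15 without scramble library 3 and 13 without tDR library 2. The 7 of the 7SK family became 0, 4 and 2 without the same libraries and 0 with the replicate block, but 21 under scaling on microRNAs alone, 17 with DESeq2 and 22 with the authors' factors. The 22 U1 and 26 Y RNA features became 25 and 44 under scaling on microRNAs alone, 32 and 35 with DESeq2, 34 and 36 with the authors' factors and 14 and 9 with the replicate block. The U2 median was also below 0 without tDR library 2 (-0.018) and with a mean count of at least 50 (-0.096). The Y RNA median was also above 0 without tDR library 3 (0.0054), with each read set taken once (0.011) and without tDR libraries 3 and 4 (0.10). Without those 2 libraries the 5S rRNA median was above 0 as well (0.032).

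**Figure D2:**
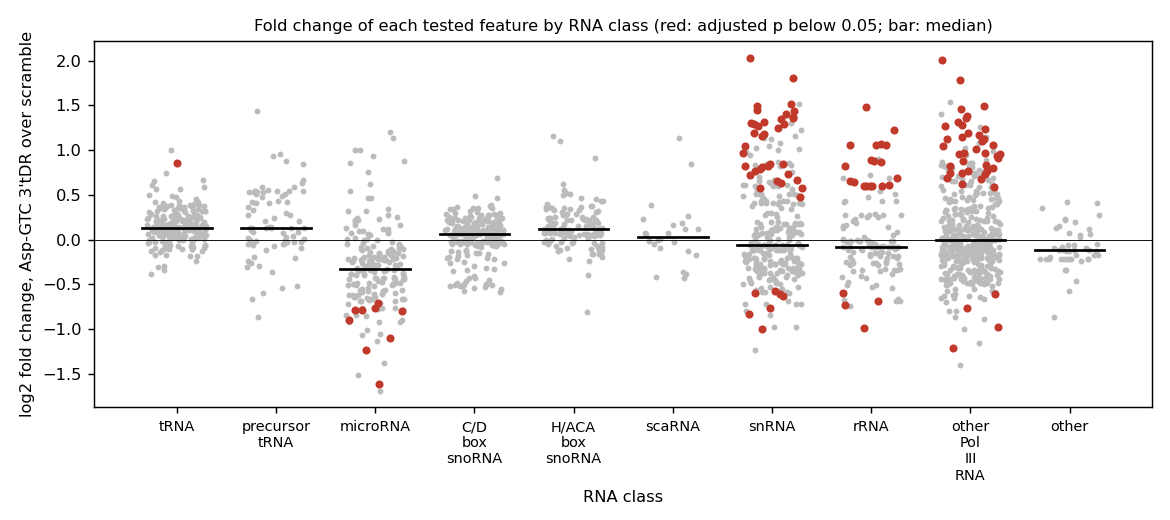
Log2 fold change of each tested feature, Asp-GTC 3′ tDR over scramble, by RNA class (TMM scaling). Each point is a feature, red points have an edgeR adjusted p below 0.05 and bars are class medians, such as -0.33 for microRNAs and 0.13 for tRNAs; under total-count scaling the tRNA median is -0.0095, and under scaling on microRNAs alone the microRNA median is 0.0047.

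A small set of microRNAs was lower in the tDR libraries. Of 196 tested microRNAs 9 fell and 0 rose (7 and 0 adjusted over the list alone). With 1 library left out the counts ran from 3 lower and 2 higher (tDR library 4) to 22 lower and 0 higher (tDR library 1). DESeq2 called 21 lower and 3 higher, and the replicate block 1 lower and 0 higher. The balance of calls turned to 5 higher and 1 lower under scaling on microRNAs alone, and also without tDR libraries 3 and 4. With all libraries the median log2 fold change was -0.33, against 0.02 over all features. Under scaling on microRNAs alone these medians were 0.0047 and 0.36. That scaling centres microRNAs near 0 by design, so calls lost under it do not bear on a fall relative to other features. The microRNA median relative to all features was -0.356 under it and -0.352 in the main fit. The paralogs hsa-miR-103a-3p and hsa-miR-107, which lie in introns of the pantothenate kinase genes and whose near-identical sequences the counting could split, went from 157 ± 22.9 to 90.6 ± 12.4 CPM and from 13.9 ± 2.24 to 5.95 ± 2.27 CPM (n = 4 each). They fell by 0.80 (SE 0.16, edgeR adjusted p = 0.0028) and 1.24 (SE 0.25, edgeR adjusted p = 0.00478) on the log2 scale. hsa-miR-128-3p, known from neurons, fell by 1.10 (SE 0.24, edgeR adjusted p = 0.00769), and hsa-miR-744-5p fell by 0.90 (SE 0.21, edgeR adjusted p = 0.0144). hsa-miR-92a-3p, a member of the cell-cycle-linked miR-17-92 cluster, went from 777 ± 133 to 450 ± 139 CPM and fell by 0.79 (SE 0.20, edgeR adjusted p = 0.0229). hsa-miR-222-3p and hsa-miR-24-3p fell by 0.78 and 0.71 (SE 0.21 and 0.19, edgeR adjusted p = 0.0277 and 0.03).

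Tested as a list with camera, microRNAs were lower than the other features (adjusted p = 4.54e-10, but adjusted p = 0.999 with an estimated correlation), as were the 18 members of the miR-17-92 family (adjusted p = 0.00165, but adjusted p = 0.999 with an estimated correlation). Without tDR libraries 3 and 4 the miR-17-92 family did not pass at the preset correlation either (adjusted p = 0.153). The limma test fry passed for 0 of the 33 lists and gave adjusted p = 0.771 for microRNAs and for the miR-17-92 family. Of the 18 members 1 fell and 17 did not pass (2 fell adjusted over the list alone); hsa-miR-18a-5p and hsa-miR-19b-3p had log2 fold changes of -0.60 and -0.32 (edgeR adjusted p = 0.0598 and 0.448). Of the 9 let-7 family members 0 passed, or 1 adjusted over the list alone, with hsa-let-7g-5p at -0.67 and hsa-let-7a-5p at -0.048 (edgeR adjusted p = 0.0513 and 0.923). The let-7 list was called lower by camera without scramble library 1 or 2 or tDR library 1 or 2 (adjusted p from 0.0216 to 0.046), but not with an estimated correlation. The 13 kidney and epithelial microRNAs, with hsa-miR-30c-5p at -0.45 and hsa-miR-194-5p at -0.57, and the 3 stress and immune microRNAs, hsa-miR-21-5p, hsa-miR-34a-5p and hsa-miR-132-3p at -0.33, -0.20 and -0.26, had 0 calls and camera adjusted p of 0.349 and 0.533. Markers of other cell types did not pass in edgeR, except hsa-miR-128-3p: hsa-miR-126-3p of endothelium had a log2 fold change of 0.47, and hsa-miR-16-5p and hsa-miR-16-2-3p, abundant in blood, -0.024 and -0.25 (adjusted p = 0.336, 0.957 and 0.807). The hypoxia-induced hsa-miR-210-3p had too few counts to be tested, with 8, 7, 7 and 19 counts in scramble libraries 1 to 4 and 8, 6, 3 and 1 in tDR libraries 1 to 4.

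The microRNA values were uneven across libraries. Against the mean of the scramble libraries, the median microRNA stood at -0.35, -0.052, 0.16 and 0.30 on the log2 scale in scramble libraries 1 to 4, and at -0.048, 0.0073, -0.68 and -0.59 in tDR libraries 1 to 4. In tDR libraries 3 and 4 the median tRNA was instead at 0.55 and 0.23. Without both of these libraries, 1 of the 9 microRNAs kept its call, hsa-miR-103a-3p, and 85 of the 94 higher features kept theirs. That fit has 4 against 2 libraries, so a lost call need not mean a lost difference. hsa-miR-107, hsa-miR-128-3p, hsa-miR-744-5p and hsa-miR-103a-3p still stood at log2 fold changes of -0.89, -0.88, -0.76 and -0.65 (edgeR adjusted p = 0.0513, 0.0705, 0.0853 and 0.0243). hsa-miR-92a-3p, hsa-miR-24-3p and hsa-miR-222-3p stood at -0.45, -0.46 and -0.44 (edgeR adjusted p = 0.143, 0.232 and 0.248). Without tDR library 4 alone 3 of the 9 were kept, and the call of hsa-miR-92a-3p was lost (adjusted p = 0.0812), as it was without scramble library 4 (adjusted p = 0.0836). The calls of hsa-miR-24-3p and hsa-miR-222-3p were lost without scramble library 3 or 4 or tDR library 3 or 4 (adjusted p from 0.0643 to 0.118), and that of hsa-miR-222-3p also without scramble library 2 (0.0577). That of hsa-miR-744-5p was lost without tDR library 4 (0.0505). The calls of hsa-miR-103a-3p, hsa-miR-107 and hsa-miR-128-3p held with any 1 library left out. With the replicate block only hsa-miR-107 kept its call. Under scaling on microRNAs alone, which centres microRNAs near 0 by design, only hsa-miR-107 kept its call among the 9.

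**Figure D3:**
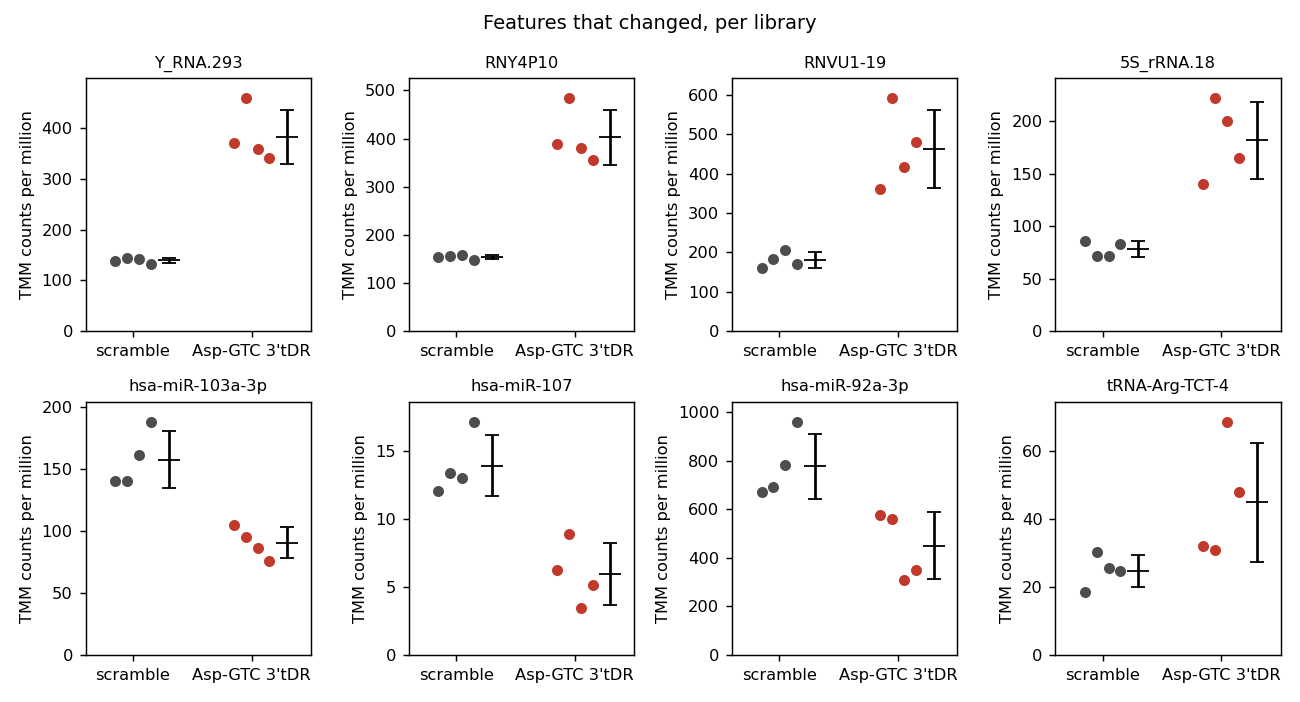
TMM-scaled CPM of 8 features in each library; points are libraries, horizontal marks are group means and whiskers are SD (n = 4). Y_RNA.293, RNY4P10, RNVU1-19 and 5S_rRNA.18 were higher in every tDR library than in any scramble library, hsa-miR-103a-3p, hsa-miR-107 and hsa-miR-92a-3p were lower, and tRNA-Arg-TCT-4 was higher.

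**Figure D4:**
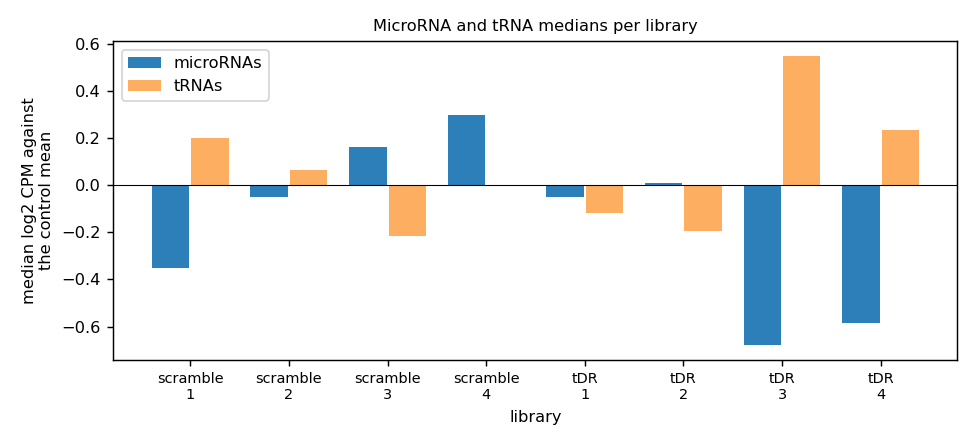
Median log2 CPM of microRNAs (blue) and tRNAs (orange) in each library, relative to the mean of the scramble libraries. MicroRNA medians are -0.68 and -0.59 in tDR libraries 3 and 4 and -0.048 and 0.0073 in tDR libraries 1 and 2.

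Among tRNAs, their precursors and the guide RNAs of rRNA modification, edgeR called 1 feature. Of 217 tRNA features 1 rose, tRNA-Arg-TCT-4, an isodecoder of the arginine tRNA, from 24.7 ± 4.83 to 44.8 ± 17.6 CPM (log2 fold change 0.86, SE 0.23, edgeR adjusted p = 0.0264). This call was not made when adjusted over the list of whole tRNAs alone, and it was lost under total-count scaling (adjusted p = 0.0932) and without any 1 scramble library, tDR library 3 or tDR library 4 (adjusted p from 0.0532 to 0.128). It was also lost with the replicate block, with a mean count of at least 50 and without tDR libraries 3 and 4, where 0 tRNA features were called. tRNA-Cys-GCA-5 and tRNA-Tyr-GTA-5 had log2 fold changes of 0.59 and 0.56 (edgeR adjusted p = 0.0598 and 0.118), and the most abundant other tRNA, tRNA-Glu-CTC-1, stood at 22350 ± 3398 and 23230 ± 5683 CPM. The list of 214 whole tRNAs outside Asp-GTC had a camera adjusted p of 0.0717, and its direction depended on the libraries. It was called higher without tDR library 2 (adjusted p = 1.13e-08), scramble library 1 (0.00151), tDR library 1 (0.00157) or scramble library 2 (0.046), and lower without tDR libraries 3 and 4 (1.8e-07). With an estimated correlation none of these calls held (adjusted p = 0.792 without tDR library 2 and 0.826 without tDR libraries 3 and 4). Of the isotype lists Cys and Asn had the lowest p (adjusted p = 0.0653 and 0.083). Cys was called higher without scramble library 2, tDR library 1 or tDR library 2 (0.0297, 0.00263 and 0.000786), again not with an estimated correlation. The other 17 lay between 0.125 and 0.954. Calls of the isotype lists also depended on the libraries. Without tDR library 2 the Ala, Asn, Glu, Leu, Lys, Ser and Thr lists were called higher (adjusted p from 0.00352 to 0.0277), as were Glu without tDR library 1 (0.00498) and Gly without scramble library 2 (0.046). Without tDR libraries 3 and 4 the Ala, Arg, Leu, Pro, Ser, Thr and Val lists were called lower (adjusted p from 0.00634 to 0.0233). None of these held with an estimated correlation. The His and SeC lists, with 2 and 1 tested features, were too small for the test. Among 78 precursor tRNAs, 203 C/D box snoRNAs, 127 H/ACA box snoRNAs and 24 scaRNAs, edgeR called 0, also when adjusted over each list alone, with camera adjusted p of 0.083, 0.954, 0.125 and 0.999. The H/ACA list was called higher without tDR library 3 (adjusted p = 0.043), tDR library 4 (0.0334) or both (0.000434). The precursor list was called higher without scramble library 2 (0.046), tDR library 1 (0.00906) or tDR library 2 (0.00711). With an estimated correlation none of these calls held (adjusted p from 0.792 to 0.998). Under scaling on microRNAs alone edgeR called 1 precursor tRNA, 1 C/D box snoRNA, 4 H/ACA box snoRNAs and 1 scaRNA higher. It called 2 precursor tRNAs higher without tDR library 1, and 1 scaRNA higher without scramble library 4 or with the authors' factors. At an unadjusted p below 0.05 these classes held 9, 5, 5 and 2 features; limma-voom called 0 in each, and DESeq2 called 1 precursor tRNA and 0 in the others. Among them, SNORD50A and SNORA2B were at 0.47 and 0.51 on the log2 scale (edgeR adjusted p = 0.172 and 0.137), SCARNA27 at 0.84 (edgeR adjusted p = 0.0786) and the precursor tRNA-Cys-GCA-2-2 at 1.43 (edgeR adjusted p = 0.0719).

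The share of counts taken by each RNA class was compared next. With 33 classes and a smallest possible p of 0.0286, at least 19 classes would have to reach that smallest p before any passed, so the adjusted test could hardly call a class and the shares are given as values. With the largest row of each gene family taken as its count, tRNAs made up 47.6 ± 2.44% of counts in the scramble libraries and 45.5 ± 6.49% in the tDR libraries (SD, n = 4 each, exact permutation p = 0.657), and rRNA 37.7 ± 2.43% and 41.7 ± 5.36% (n = 4 each, exact permutation p = 0.229). MicroRNAs took 2.84 ± 0.807% and 1.98 ± 0.675% (n = 4 each, exact permutation p = 0.143) and snRNAs 6.57 ± 0.422% and 5.76 ± 0.878% (n = 4 each, exact permutation p = 0.2). The tyrosine tRNA share, which came from tRNA-Tyr-GTA-5 alone, and the antisense tRNA share were higher in 4 of 4 tDR libraries than in any scramble library (1.35-fold and 3.71-fold, exact permutation p = 0.0286 and adjusted p = 0.471 for both, n = 4 each). These shares were 0.00339% and 9.56e-05% of the scramble counts, and the antisense share was 0 in scramble libraries 2 and 3. tRNA-Tyr-GTA-5 did not pass edgeR (adjusted p = 0.118), and the list of 9 tyrosine tRNA features had a camera adjusted p of 0.585. Leaving out tDR library 2 turned the tRNA difference from -2.12 to 0.86 percentage points.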

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

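The tests of the scaling, of the 2 tDR libraries and of the splits were chosen after the result was seen; the word test and the mimic tests were written before it.

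Among 212 groups of 4 libraries, 10 held a library far from the other 3, where about 1 in 20 groups, or 11, would do so by chance. The measure is the gap to the nearest library over the whole range, set against the 95% critical value of Dixon for 4 samples. In the tDR group these were Y_RNA.122 (gap ratio 0.916, tDR library 3 at 7.51 CPM against 9.50 to 9.68), RNU1-130P (0.846, tDR library 2 at 7.17 against 3.13 to 3.76), hsa-miR-744-5p (0.837, tDR library 2 at 14.5 against 8.31 to 9.32), SCARNA27 (0.847, tDR library 1 at 6.41 against 4.73 to 4.99) and the antisense tRNA share (0.861, tDR library 4 at 0.000628% against 0.000232 to 0.000287%). In the scramble group they were RNU6ATAC26P (0.836, library 4 at 7.23 CPM against 5.84 to 6.07), 5_8S_rRNA.9 (0.848, library 1 at 10.3 against 6.10 to 6.73), RN7SL1 (0.837, library 1 at 1775 against 1059 to 1176), SNORD3A (0.854, library 1 at 615 against 399 to 430) and the histidine tRNA share (0.982, library 1 at 1.28% against 0.908 to 0.915%). The entry scr2, outside the gene counts, was also seen in the tDR libraries, at 17.6 CPM or 0.362% of its level in the scramble libraries.

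The first pattern is the rise of U1, U2, Y4 and 5S related features. Scaling is argued against as the whole cause, since the lowest share of the 94 risen features still called under another scaling was 57.5%. That was under total counts, with 17 of 22 U1, 9 of 11 U2 and 11 of 14 5S features still called higher. Of the 26 Y RNA features only 11 were, so the argument does not cover these. One read species counted at many copies may account for part of it, in the 5S and Y4 families. The limit written beforehand was a shared word in at least 80% of a family's risen sets. Of the 3 families with enough sequences, 2 passed it, 5S and Y4. The Y4 test covered 18 features named after RNY4, 7 of them risen, and not the other Y RNA features. Of the 9 risen 5S sets, 88.9% hold the same 20-base word of RNA5S1 (bases 46 to 65), against 11.8% of the others (permutation p = 5e-04). Of the 6 risen Y4 sets, 100% hold bases 11 to 30 of RNY4, against 18.2% of the others (permutation p = 0.0135). For U1 the shares were 68.4% and 12% for bases 119 to 138 of RNU1-1 (permutation p = 0.0015), so U1 stayed below the limit. For U2 they were 71.4% and 11.1% for bases 98 to 117 of RNU2-1 (permutation p = 0.0425). U2 was set aside because 74.5% of its features had a sequence, below a minimum of 80%. An effect of the mimic on such fragments stays open, as does any technical change in which fragments were captured.

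The second pattern is the fall of microRNAs. Without tDR libraries 3 and 4 the microRNA median lay at -0.123 relative to all features (221 microRNAs), against -0.352 with all libraries (196 microRNAs). These 2 libraries had the lowest microRNA medians, -0.68 and -0.59, against -0.048 and 0.0073 in tDR libraries 1 and 2. Leaving them out therefore had to shrink the fall, so the comparison cannot show whether the fall comes from them alone. They may have been captured or handled differently, but the labels give no batch. Some called microRNAs were also lower in tDR libraries 1 and 2. hsa-miR-103a-3p stood at 105 and 95.1 CPM in tDR libraries 1 and 2 against 140 to 188 in the scramble libraries, and hsa-miR-107 at 6.27 and 8.89 against 12.1 to 17.2. hsa-miR-128-3p, hsa-miR-744-5p, hsa-miR-92a-3p and hsa-miR-24-3p were also lower in every tDR library than in any scramble library. hsa-miR-222-3p was not, at 71.4 CPM in tDR library 1 against 64.8 in scramble library 1. Apart from hsa-miR-24-3p and hsa-miR-222-3p, chosen after their values were seen, these microRNAs were named by a rule that requires groups not to overlap. So the lack of overlap is no test of whether the 2 libraries carry the fall. An effect of the mimic on microRNAs stays open and was not tested apart from this.

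The third pattern is the absence of a called rise of tRNA-Asp-GTC-2. Mimic reads at the level of scr2 would add 0.242 on the log2 scale, inside the 95% interval of -0.23 to 0.44, so mimic reads hidden under the endogenous tRNA cannot be told apart from none. At tRNA-Asp-GTC-1 the same reads would add 2.01, above the interval of -0.14 to 0.68, which argues against their being counted there at that level. Whether the mimic was captured at all stays open.

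Over the 35 splits of the 8 libraries, the real split called 118 features and the highest other split 6, so 1 split reached the real count. That is the smallest share 35 splits can give. It argues against a random division of the libraries as the source of the calls, but no more strongly than 1 in 35. The test, chosen after the result was seen, does not separate the mimic from anything else that differed between the groups.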

How the results depend on the processing

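Each read set taken once, the authors' factors, tDR libraries 3 and 4 left out, sums over all features and the sign flips were chosen after seeing the data. The count of 118 changed features lay between 93 and 158 under the scalings, filters and limma-voom; it was 194 with the DESeq2 Wald test, 188 on the deposited normalized signal, 185 with the authors' factors and 39 with the replicate block, and 65 to 164 without 1 library. The block called 38 higher and 1 lower, all 39 among the 118. Correlations of same-numbered deviations were -0.34, -0.18, -0.26 and -0.12, so same-numbered libraries did not deviate alike. Whether the numbers pair samples is not given by the labels. Of 33 lists 2 passed, against 0 with an estimated correlation, 4 without a filter (adjusted over the same 33; 3 of the 39 then testable passed when adjusted over all 39), 10 without tDR libraries 3 and 4 and 2 to 14 without 1 library (4 without scramble library 1, 8 without scramble library 2 or tDR library 1, 14 without tDR library 2). The class shares could hardly pass in any setting, since 19 of 33 classes would have to reach the smallest p and sign flips of 4 differences cannot go below 0.125, so their lack of calls says nothing about stability. Without 1 library the tRNA share difference ran from -4.15 to 0.86 and the microRNA one from -1.18 to -0.571 percentage points. With all libraries they were -2.12 and -0.862, but -6.43 and -0.681 on the deposited normalized values, -0.366 and -0.222 as sums over all features and -2.04 and -0.99 with Asp-GTC left out. None of the 31 called named features turned in the 21 settings where it had a value, while 18 of 53 uncalled ones did. The called ones were chosen for large changes or low p, and uncalled ones included values near 0, such as 0.0033 for SCARNA16. So this contrast follows from the choice and is no sign of stability. Of the 31 called ones, 12 lost the call under TMM on microRNAs, 12 without tDR libraries 3 and 4, 14 with the block and 2 under total counts.

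Log2 values that turned were, under DESeq2 size factors, tRNA-Asp-GTC-2-9 -0.0085 and SCARNA16 -0.012; under total counts, tRNA-Asp-GTC-2 -0.044, tRNA-Asp-GTC-2-9 -0.16, SCARNA16 -0.15, tRNA-Glu-CTC-1 -0.083 and RNY3 -0.13; under TMM on microRNAs, tRNA-Asp-GTC-3 0.065, hsa-let-7a-5p 0.28, hsa-miR-19b-3p 0.017, hsa-miR-16-2-3p 0.12, hsa-miR-16-5p 0.32, hsa-miR-34a-5p 0.15, hsa-miR-132-3p 0.050, RN7SL1 0.16, SNORA33 0.33, U2.10 0.27, RNU2-1 0.27 and RNA5S1 0.24. With a mean count of at least 50 they were tRNA-Asp-GTC-2-9 -0.037, SCARNA16 -0.045 and RNY3 -0.022, and with the DESeq2 Wald test tRNA-Asp-GTC-2-9 -0.0092 and SCARNA16 -0.0092. With the block SCARNA16 was at -0.0012. On the deposited signal, tRNA-Asp-GTC-2 was at -0.095, tRNA-Asp-GTC-2-9 -0.19, hsa-miR-16-5p 0.031, SNORA33 0.025 and tRNA-Glu-CTC-1 -0.16. With each read set once, hsa-miR-16-5p was at 0.029 and SNORA33 0.048. With the authors' factors, tRNA-Asp-GTC-2 was at -0.10, tRNA-Asp-GTC-2-9 -0.22, hsa-miR-16-5p 0.016, SNORA33 0.028 and tRNA-Glu-CTC-1 -0.16. Without tDR libraries 3 and 4, tRNA-Asp-GTC-2 was at -0.015, tRNA-Asp-GTC-2-9 -0.16, tRNA-Asp-GTC-2-8 -0.14, hsa-let-7a-5p 0.21, hsa-miR-19b-3p 0.033, hsa-miR-16-5p 0.23, hsa-miR-21-5p 0.11, hsa-miR-34a-5p 0.058, hsa-miR-132-3p 0.17, SCARNA16 -0.028, tRNA-Glu-CTC-1 -0.27 and RNY3 -0.073. Without 1 library the ranges were tRNA-Asp-GTC-2 0.0050 to 0.19, tRNA-Asp-GTC-2-9 -0.094 to 0.11, RN7SL1 -0.28 to 0.019, RNY3 -0.074 to 0.076, SCARNA16 -0.051 to 0.043, SNORA33 -0.091 to 0.014, hsa-let-7a-5p -0.19 to 0.062, hsa-miR-16-5p -0.18 to 0.089, hsa-miR-34a-5p -0.41 to 0.014 and tRNA-Glu-CTC-1 -0.090 to 0.17. The cause was not tested. The planned balance of 3′ to 5′ tRNA fragments was not run, as the files do not separate them, and depth left 1201 features untested.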

Other observations

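The families below were chosen after the values were seen. The minor spliceosome's U6atac features had a median log2 fold change of -0.65, with 2 of 6 called lower, 0 of 7 without tDR library 4, 1 without scramble library 2 or 3 or tDR library 3, and 4 of 7 without tDR library 1 (camera adjusted p = 5.45e-05, but adjusted p = 0.384 with an estimated correlation). U6 features, the catalytic snRNA of the major spliceosome, had a median of -0.21, which turned to 0.12 under scaling on microRNAs alone, with 2 called higher and 5 lower of 142, or 16 and 12 of 160 without tDR library 1 and 1 and 0 of 168 without tDR library 4 (camera adjusted p = 0.000145, but adjusted p = 0.746 with an estimated correlation). Copies of 7SL, the signal recognition particle RNA, had a median of 0.31 with 4 of 55 called higher (camera adjusted p = 0.00621, but adjusted p = 0.746 with an estimated correlation), although RN7SL1 itself was at -0.18. Under total counts 0 of the 7SL features were called higher and 1 lower, and 0 were higher without scramble library 2, scramble library 3 or tDR library 4. Without tDR library 2 or 3 the count was 1, and without scramble library 1 or tDR library 1 it was 2. The 4 vault RNA features had a median of -0.29, which turned to 0.065 under scaling on microRNAs alone (camera adjusted p = 0.0161, but adjusted p = 0.384 with an estimated correlation).

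On the first principal component (33.5% of the variance) tDR libraries 1 to 4 stood at -1.26, 5.0, 14.7 and 14.5 and scramble libraries 1 to 4 at -3.54, -7.23, -12.3 and -9.85. The ratio of the authors' tRNA factor to their factor for other features was 0.981, 1.02, 0.904 and 0.791 in scramble libraries 1 to 4 and 0.904, 0.88, 1.47 and 1.22 in tDR libraries 1 to 4.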
